A study of Homo sapiens with 12 samples.

How the data were processed

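The series measured RNA levels in MOLM-14 cells, a human acute myeloid leukemia line known to carry a KMT2A rearrangement and an internal tandem duplication of FLT3. It holds 12 RNA-seq libraries in 2 experiments. In the first, cells infected with a lentivirus for a control shRNA (shControl) or for an shRNA against DDX5 (shDDX5) were collected after 96 hours. In the second, cells were kept for 6 hours in 0.1% DMSO or in 100 nM RX-5902, a small molecule described as acting on phosphorylated DDX5. Each of the 4 groups had 3 libraries, which the labels call biological replicates, so the p-values measure the spread between those replicates. Groups and replicate numbers were taken from the labels, and no control library was shared between the experiments.

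Per the labels' protocols, RNA was extracted with Trizol and RNeasy columns with a DNase step, and libraries were made with the MGIEasy Fast RNA kit. The deposited values were raw read counts per gene, 1 column per library, in 1 table per experiment, and the authors had not normalized them. The submitters' processing notes name Trim Galore 0.6.7, STAR 2.7.9a, Picard 2.8.0, featureCounts from Subread 2.0.3, R 4.4.2 and DESeq2 1.46.0, with the build GRCh38.p13. The annotation release, the strand setting of the counting, the type of RNA selection and the handling of duplicate and multi-mapping reads were not given in the sources used here. Reads from overlapping genes on opposite strands may therefore have been mixed. Some genes with such a partner or with near-identical copies are named as uncertain in the text. Other named genes also have such a partner and are not marked there, such as FTH1, PSMD7, SQSTM1, HOXA10, TAP1 and ITPR3.

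Each table held 61906 genes. In both tables the line of 1 gene was wrapped over 3 lines and was rejoined before use. Gene symbols were matched by the versioned identifier for 59984 genes and by the identifier without its version for 1819, while 103 had no match and keep their identifier. Gene classes came from a GENCODE annotation that held 58352 of the identifiers, and for the rest from RefSeq where it had the gene. By these classes 19879 genes were protein-coding. Coordinates are the outermost exon ends in the deposited tables, on GRCh38, counted from 1. GC content was taken from the longest transcript of each gene in GENCODE release 29, since no genome sequence was at hand.

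Total counts per library ran from 17603589 to 19674098 in the knockdown experiment and from 20264250 to 20367575 in the drug experiment. Mitochondrially encoded genes took 5.19 to 10.3% of the counts, and genes annotated as ribosomal RNA, mitochondrial ones included, 0.469 to 1.31%. Between replicates, the chi-square per gene over genes with at least 10 counts lay between 1.76 and 6.62 for every pair except the pairs of shDDX5 replicate 1 with replicates 2 and 3, at 52.5 and 52.7. No pair of replicates was within sampling noise, so all 12 libraries were counted separately.

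Each experiment was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's default expression filter, TMM factors scaled the libraries, and group differences were tested with the quasi-likelihood F test, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that experiment. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled, and means carry the SD over 3 libraries. A test of the difference used all 12 libraries with 4 group means and compared the change of shDDX5 over shControl with the change of RX-5902 over DMSO.

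Lists of genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists with at least 5 measured members, and again with the correlation estimated from the data. The 50 lists covered mitochondria, energy metabolism, stress responses, apoptosis, cell cycle, RNA and ribosome factors, immune signalling, leukemia and myeloid differentiation, lipid synthesis and markers of other cell types. The lists, the tests, the rule for named genes and the alternative settings were fixed before the data were examined. A further 6 lists were written after the results had been seen and stand only among the closing observations.

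The genes named in the text followed a rule with 5 parts. They were DDX5, DDX17 and 11 genes of apoptosis, MYC, Wnt signalling and the cell cycle; the 6 protein-coding genes with the largest rise and the 6 with the largest fall in each experiment, with a mean of at least 5 CPM and no overlap between groups; up to 3 called members with the smallest p from each list that camera called or that held at least 3 called genes; the 5 genes in each direction with the largest shared change; and the 3 in each direction with the largest difference between the experiments. Genes outside the rule are said to have been chosen after their values were seen. Genes of the Y chromosome and XIST were left out.

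The code was tested on simulated data drawn from the means, dispersions and library sizes of the real genes, with 200 genes changed by known folds in each experiment. In the simulated shDDX5 comparison edgeR recovered 44.9% of changes of 1.5-fold, 83.0% of 2-fold and 97.9% of 4-fold, with 9 false calls among 14230 genes. The simulated RX-5902 comparison gave 77.6%, 90% and 100%, with 10 false calls among 13711 genes, and the test of the difference, with 90 to 93 changed genes at each fold, gave 35.6%, 75% and 92.5%, with 12 false calls among 13227 genes. Of the smallest simulated changes, below 1.5-fold, 0% were recovered for shDDX5, 71.4% for RX-5902 and 4.44% for the difference. Camera called the list that had been moved in both simulations, and also 1 of 40 random lists in each. The simulations changed a far smaller share of genes than was called in the real data (56.7% and 64.1%). They also held no outlying library and no correlation between genes. The recovered shares are therefore a check of the code and not the power of the real comparisons.

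Alternative settings were DESeq2 1.42.0, DESeq2 size factors or library totals in place of TMM, no expression filter or a stricter one (5 CPM in 3 libraries), a test against a fold of 1.2, a correction for exon length, the replicate number as a block with and without that correction, all 12 libraries in 1 fit, protein-coding genes only, a mean of at least 10 CPM for the comparison between experiments, and leaving out each library in turn.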

Results

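Cells infected with the shRNA against DDX5 held 4.55-fold less DDX5 RNA after 96 hours than cells with the control shRNA (log2 fold change -2.19, standard error 0.08, 3 libraries per group, edgeR adjusted p = 3.44e-06). DDX5 encodes an RNA helicase of transcription and splicing (chr17:64498254-64508199). It stood at 755, 718 and 730 CPM in the 3 shControl libraries and at 159, 164 and 161 CPM in the 3 shDDX5 libraries. Its closest paralog DDX17 fell by 0.43 (SE 0.09, adjusted p = 0.00293 with edgeR). With the knockdown, genes of cell division and ribosome assembly fell as groups, and interferon genes rose. The groups held no other shRNA against DDX5 and no rescue of DDX5. Other effects of the shRNA can therefore not be told apart from the loss of DDX5. In all, edgeR called 8204 of 14463 tested genes (56.7%), of which 4105 rose and 4099 fell, and 1566 rose and 1491 fell by at least 2-fold. The DDX5 and CEP95 genes overlap by 252 bases, and DDX5 and DDX17 have similar sequences, so reads could have been exchanged between them.

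Among protein-coding genes with a mean of at least 5 CPM and no overlap between groups, the largest rise was that of SLPI, a secreted inhibitor of neutrophil proteases (chr20:45252239-45254564), at 19.2-fold (log2 4.26, SE 0.21), from 6.10 ± 0.743 to 117 ± 30.4 CPM (mean ± SD, n = 3). PLCB4, a phospholipase C, rose by 4.10 on the log2 scale (SE 0.12), MXRA8, a cell adhesion protein and virus receptor, by 3.71 (0.31), LAIR2, a soluble collagen receptor, by 3.27 (0.18), TBX1, a transcription factor of development, by 3.26 (0.22), and the histone gene H2BC12 by 3.04 (0.13). The largest fall under the same limits was that of SPOCK1, a matrix proteoglycan (chr5:136975298-137598379), with a log2 fold change of -4.53 (SE 0.21). CD48, a ligand of the immune receptor CD244, was 13.2-fold lower, and ITPR3, a calcium channel of the endoplasmic reticulum, 8.07-fold lower. SV2A, a vesicle protein, C1orf216, of little known function, and the cannabinoid receptor CNR2 were 7.74-fold, 7.45-fold and 7.28-fold lower.

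Of 36 measured genes of mitosis, 35 fell and 0 rose in shDDX5 cells, with a median log2 fold change of -1.86 (camera adjusted p = 3.78e-36). Examples were the spindle kinesins KIF2C (-2.18) and KIF23 (-2.28) and the cyclin CCNA2 (-1.70). Among 30 targets of the DREAM complex and E2F, which act in DNA replication, 29 fell and 0 rose (median -1.87, camera adjusted p = 7.56e-35), among them the helicase subunits MCM6 (-2.15) and MCM7 (-2.13) and the ribonucleotide reductase gene RRM1 (-2.28). MYC itself, the growth regulator at chr8:127735434-127742951, was 2.18-fold lower (log2 -1.12, SE 0.08, edgeR adjusted p = 1.89e-05), at 426 ± 20.5 CPM in shControl and 196 ± 7.61 CPM in shDDX5 cells. Of 35 MYC targets 27 fell and 1 rose, or 30 and 1 when adjusted over the list alone (median -0.78, camera adjusted p = 9.08e-09, and adjusted p = 0.0591 with an estimated correlation), with MCM5 (-1.81), MCM4 (-1.90) and the nucleolin gene NCL (-1.79) as examples. The cyclin gene CCND1 was 5.27-fold lower (log2 -2.40, SE 0.14), and the cell cycle inhibitor CDKN1A (chr6:36676460-36687337) rose 2.68-fold (log2 1.42, SE 0.11, edgeR adjusted p = 2.79e-05). CCND1 shares 497 bases with LTO1, which makes its level less certain.

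Most genes that make ribosomes and process RNA fell in shDDX5 cells. Of 49 ribosome biogenesis genes 34 fell and 3 rose (median -0.57, camera adjusted p = 4.07e-06), among them the assembly factor RRS1 (-1.58) and the nucleolar helicases DDX31 (-1.24) and DDX27 (-1.17). The list of 34 DEAD-box helicases, which includes DDX5 itself, had 22 that fell and 3 that rose (median -0.52, camera adjusted p = 7.31e-05, and adjusted p = 0.126 with an estimated correlation), and the spliceosomal helicase gene DDX23 fell by 1.64. In the spliceosome and SR protein list 29 of 45 fell and 4 rose (median -0.41, camera adjusted p = 0.000252, and adjusted p = 0.126 with an estimated correlation), including SF3A1 (-1.67), HNRNPH1 (-1.19) and HNRNPA2B1 (-1.04). Factors of R-loops and RNA decay had 14 of 25 fallen and 1 risen (median -0.43, camera adjusted p = 0.00365, and adjusted p = 0.126 with an estimated correlation), such as the exosome gene EXOSC2 (-1.25) and the RNase H gene RNASEH2B (-0.90). Without shDDX5 replicate 1 the R-loop list had 18 fallen and 4 risen of 26 genes, and tubulins had 10 fallen and 2 risen of 12. Tubulins had 8 of 11 fallen and 1 risen (median -0.65, camera adjusted p = 0.0219, and adjusted p = 0.340 with an estimated correlation), with TUBA1B at -0.97, and without shControl replicate 2 the camera adjusted p was 0.0559.

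Most measured leukemia stem cell genes fell with the knockdown, and most genes of mature myeloid cells rose. Of 18 KMT2A-fusion and stemness genes 11 fell and 4 rose (median -0.58, camera adjusted p = 0.000448, and adjusted p = 0.126 with an estimated correlation). MEIS1, a cofactor of HOX proteins in leukemia, was 6.63-fold lower, HOXA10 fell by 2.01 and the stem cell factor gene ZNF521 by 2.39. In the monocyte list 14 of 25 rose and 6 fell, 16 and 6 when adjusted over the list alone (median 0.45, camera adjusted p = 0.0275, and adjusted p = 0.247 with an estimated correlation), with lysozyme LYZ at 1.92, the scavenger receptor CD36 at 1.27 and the integrin ITGAM at 1.27. Granulocyte genes rose in 12 of 16 cases and fell in 0 (median 0.73, camera adjusted p = 0.000719, and adjusted p = 0.230 with an estimated correlation), such as the granule enzymes PRTN3 (2.28) and MPO (0.86) and the nuclear protein gene MNDA (1.28), and 2 fell without shDDX5 replicate 1. HLA class I genes rose in 8 of 11 and fell in 0 (median 0.69, camera adjusted p = 0.0134, and adjusted p = 0.229 with an estimated correlation), for example the peptide transporter TAP1 (1.86) and HLA-C (1.18). In this list shDDX5 replicate 1 lay 0.54 above replicates 2 and 3, with a median change of 0.95 against 0.51, and without it 8 still rose and 0 fell.

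**Figure D1:**
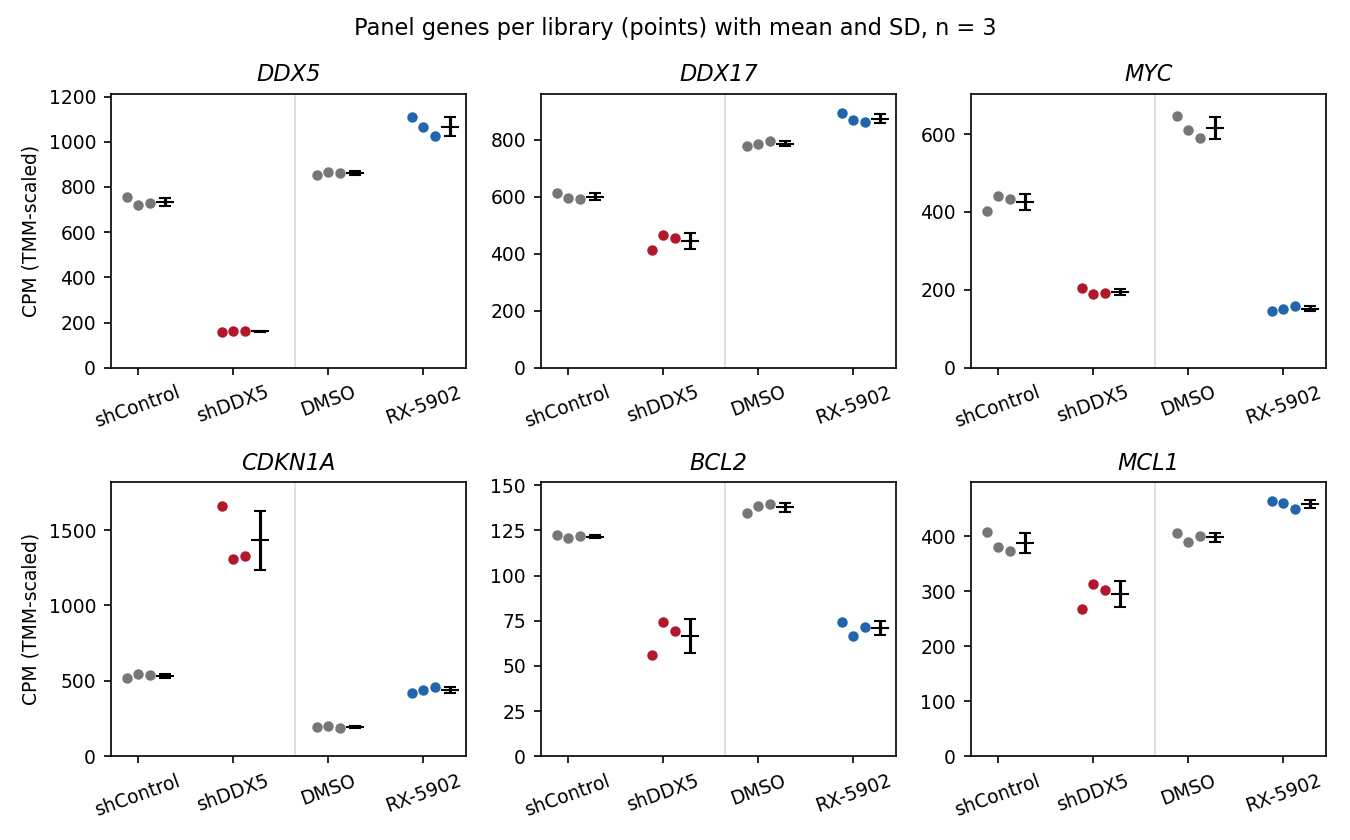
TMM-scaled CPM of DDX5, DDX17, MYC, CDKN1A, BCL2 and MCL1 in each of the 12 libraries, with the mean and SD of each group (n = 3). The knockdown and drug experiments each have their own control group.

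Interferon response genes rose in 27 of 32 cases and fell in 0 in shDDX5 cells (median 1.31, camera adjusted p = 1.86e-14). OAS2, a sensor of double-stranded RNA, rose by 1.87, the ADP-ribosyltransferase gene PARP9 by 1.71 and the regulator IRF7 by 2.27. Lysosome and autophagy genes rose in 20 of 24 and fell in 2 (median 0.83, camera adjusted p = 1.17e-08, and adjusted p = 0.187 with an estimated correlation), with the lysosomal enzymes CTSA (5.04-fold) and NEU1 (log2 2.37) and the channel MCOLN1 (1.74). Targets of p53 had 19 of 27 risen and 3 fallen (median 0.56, camera adjusted p = 9.63e-05, and adjusted p = 0.126 with an estimated correlation), among them the antiproliferative gene BTG2 (1.71), FUCA1 (1.36) and SESN1 (0.93). For immediate early genes the counts were 20 risen and 2 fallen of 28 (median 0.61, camera adjusted p = 1.63e-05, and adjusted p = 0.230 with an estimated correlation), with the transcription factors JUN at 2.68 and EGR2 at 1.58. Replication-dependent histones rose in 7 of 9 and fell in 0 (median 2.08, camera adjusted p = 2.01e-05, and adjusted p = 0.25 with an estimated correlation), such as H2AC6 (2.56) and H2BC21 (2.59). Only these 9 of 31 listed histones passed the expression filter, and they summed to 16.9 CPM in shControl and 67.4 CPM in shDDX5. Without shDDX5 replicate 1, 7 p53 targets and 5 immediate early genes fell.

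Stress response lists split in their movement. Antioxidant and NRF2 targets rose in 12 of 19 and fell in 0 (median 0.65, camera adjusted p = 0.000394, and adjusted p = 0.229 with an estimated correlation), led by heme oxygenase HMOX1 at 7.47-fold, and 3 fell without shDDX5 replicate 1. Genes of the unfolded protein response rose in 12 of 20 and fell in 4 (median 0.60, camera adjusted p = 0.00319, and adjusted p = 0.126 with an estimated correlation), among them CRELD2 (2.29) and the chaperone HSPA5 (0.98). Camera did not call ATF4 targets (12 of 29 rose and 7 fell, adjusted p = 0.287), where the secreted hormone gene STC2 fell by 1.13, or heat shock genes (3 of 15 rose and 7 fell, adjusted p = 0.398), where the co-chaperone BAG3 rose by 1.48 and HSPH1 fell by 1.01. Hypoxia targets (5 rose and 4 fell of 13) and proteasome genes (5 and 5 of 31) had camera adjusted p values of 0.940 and 0.937, and without shDDX5 replicate 1 proteasome genes had 6 risen and 18 fallen and ATF4 targets 14 and 11.

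BCL2, the anti-apoptotic gene at chr18:63123346-63320128, was 1.83-fold lower in shDDX5 cells (log2 -0.87, SE 0.11, edgeR adjusted p = 0.000296), at 122 ± 0.854 CPM in shControl and 66.5 ± 9.44 CPM in shDDX5. MCL1, a second survival gene of the family (chr1:150560895-150579738), fell by 0.40 (SE 0.09, edgeR adjusted p = 0.00643), and BCL2L1, which encodes BCL-XL, rose by 0.56 (SE 0.08, edgeR adjusted p = 0.000634). The survival gene BCL2A1 rose by 0.46 (SE 0.16, edgeR adjusted p = 0.0354), with adjusted p values of 0.0524, 0.134 and 0.111 without shControl replicates 1, 2 and 3, and it was at 0.15 (0.340) after the length correction. BAX, which opens the outer mitochondrial membrane, rose by 0.55 (SE 0.16, edgeR adjusted p = 0.0203), with 0.0889, 0.0602 and 0.0659 without the same libraries. Without shDDX5 replicate 1, BAX was at 0.32 and BCL2A1 at 0.27. PMAIP1, which encodes the MCL1 antagonist NOXA, rose by 0.33 (SE 0.09, edgeR adjusted p = 0.0135, and 0.0814 without shControl replicate 2), and was at 0.19 (0.101) with the length correction and a replicate block. None of MCL1, BCL2A1, BAX and PMAIP1 was called against a fold of 1.2 (edgeR adjusted p = 0.0648, 0.107, 0.0580 and 0.163). BBC3, which encodes PUMA, was at 0.36 (SE 0.18, edgeR adjusted p = 0.119), with 0.0402 without shDDX5 replicate 3, 0.0460 in 1 fit of all 12 libraries, and a value of 0.12 (0.309) without shDDX5 replicate 1. The BH3-only gene BMF rose by 0.88, the pore-forming gene BAK1 by 0.78, BIK fell by 0.65 and the inhibitor of apoptosis BIRC5 fell by 2.29. As lists, 5 anti-apoptotic genes (2 rose and 3 fell) and 10 pro-apoptotic genes (4 rose and 1 fell) had camera adjusted p values of 0.856 and 0.444. Without shDDX5 replicate 1, 4 pro-apoptotic genes rose and 2 fell.

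Mitochondrial lists were not called by camera in the knockdown with all 6 libraries and no block, although single genes changed. The mitochondrial transcription factor gene TFAM fell by 1.30, the fusion gene OPA1 by 1.09 and the helicase gene TWNK by 0.78, while the autophagy receptor SQSTM1 rose by 1.13 and the kinase ULK1 by 1.16. Of 28 mitochondrial biogenesis genes 13 fell and 4 rose (median -0.33, camera adjusted p = 0.289, and 0.0344 without shDDX5 replicate 1). Complex I had 5 risen and 5 fallen of 37 (camera adjusted p = 0.736), complexes II to V 7 and 2 of 40 (0.5), the mitochondrial ribosome 18 and 18 of 75 (0.902) and the mtDNA-encoded proteins 5 and 0 of 13 (median 0.42, 0.209). Members that moved were NDUFV3 (0.84), NDUFAB1 (-0.85), COX7C (1.22), MRPL19 (-1.47), MRPS28 (-1.48) and MT-CYB (0.94). Replicate 1 of shDDX5 lay above replicates 2 and 3 in these groups, by a median log2 of 0.54 for complex I, 0.56 for complexes II to V, 0.67 for the mtDNA-encoded proteins and 0.43 for the mitochondrial ribosome. Without it, 8 rose and 17 fell in complex I, 8 and 18 in complexes II to V, 20 and 37 in the mitochondrial ribosome, and 7 and 0 among the mtDNA-encoded proteins, whose median was then 0.17. With the replicate number as a block camera called the mtDNA-encoded list (adjusted p = 0.0433).

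Energy metabolism moved at single genes. In the TCA cycle 7 of 20 fell and 3 rose (camera adjusted p = 0.335), with the pyruvate carboxylase gene PC at -1.19 and IDH3A at -1.20. Glycolysis had 7 of 20 fallen and 0 risen (camera adjusted p = 0.162), including ENO2 (-1.75), the glucose transporter SLC2A1 (-0.75) and PDK1 (-0.81). Without shDDX5 replicate 1 the TCA cycle had 12 fallen and 6 risen and glycolysis 14 and 3. Fatty acid oxidation had 6 risen and 3 fallen of 15 (camera adjusted p = 0.444), with HADHB at 0.95 and HADH at -1.13, and mitochondrial dynamics 7 and 3 of 18 (0.333), which became 8 and 5 and 10 and 6 without that library. For fatty acid synthesis the counts were 1 risen and 6 fallen of 10 (camera adjusted p = 0.0782, and 0.0358 without shDDX5 replicate 1), with the desaturases FADS2 (-3.13) and SCD (-1.43). Cholesterol synthesis had 11 of 21 risen and 3 fallen (camera adjusted p = 0.0818), with DHCR7 at 0.85 and HMGCS1 at -1.08.

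At the main settings the Wnt, NF-kB, MAPK and STAT5 lists were not called in shDDX5 cells. Wnt targets had 4 risen and 4 fallen of 9 (camera adjusted p = 0.0529), with values of 0.0458 and 0.0483 without shControl replicates 2 and 3, and 0.0358 and 0.0470 without shDDX5 replicates 1 and 3. The camera adjusted p was 0.0268 with the stricter filter and 0.229 with an estimated correlation. CTNNB1, which encodes beta-catenin, rose by 0.62 (SE 0.08, edgeR adjusted p = 0.000358). Inflammatory NF-kB genes had 7 risen and 5 fallen of 19 (camera adjusted p = 0.657), where the cytokine TNF fell by 2.20 and CD83 rose by 1.33. MAPK output genes had 6 and 6 of 15, where the phosphatase DUSP4 rose by 1.76 and ETV4 fell by 1.64, and STAT5 targets 5 and 4 of 12, where CCND3 fell by 1.51 (camera adjusted p = 0.904 for each list). Cytosolic ribosomal protein genes had 3 risen and 2 fallen of 74 (camera adjusted p = 0.535), with RPL7 at -1.09 and RPL28 at 0.73 (0.48 without shDDX5 replicate 1), and 13 risen and 32 fallen without shDDX5 replicate 1, which lay above the other replicates by a median of 0.55. For snoRNA host genes 3 rose and 1 fell of 16 (camera adjusted p = 0.904), and 4 and 9 without that library, while NF-kB genes had 9 and 9.

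Markers of other cell types were read as a measure of identity and purity. Mast cell and eosinophil genes had 3 of 6 risen (camera adjusted p = 0.0585), and summed to 15.7 ± 1.23 CPM in shControl and 22.1 ± 2.39 CPM in shDDX5, with the eosinophil peroxidase gene EPX at 3.10. The other 2 risen genes had at most 2 reads in any shControl library. The list had adjusted p values of 0.0409 and 0.0472 without shControl replicates 2 and 3, and 0.0292 and 0.0350 without shDDX5 replicates 2 and 3. With the replicate number as a block it was 0.0384, without shDDX5 replicate 1 it was 0.28, and the adjusted p was 0.230 with an estimated correlation. T and NK cell markers summed to 99.2 ± 3.89 CPM in shControl and 140 ± 24.0 CPM in shDDX5 (n = 3), where NKG7 rose by 1.08 and CD3D fell by 2.54. Megakaryocyte markers summed to 9.61 ± 0.666 and 5.96 ± 1.87 CPM, with the platelet receptor gene GP1BA at -2.99. Erythroid markers summed to 28.6 and 30 CPM, fibroblast markers to 9.76 and 12.3 CPM and B cell markers to 2.87 and 2.63 CPM. Markers of packaging and epithelial cells summed to 12.4 and 9.16 CPM, and L1CAM of that list fell by 2.11. Of 4 HLA class II genes 1 rose, HLA-DMB. GP1BA, L1CAM and HLA-DMB were chosen as examples after their values were seen. These lists other than the mast cell list had fewer than 5 measured members and were not tested.

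Replicate 1 of shDDX5 stood apart from replicates 2 and 3 across the transcriptome. The first principal component held 78.5% of the variance and separated the groups, and the second held 14.2% and separated this library. On the first it also lay furthest out, at 63.1 against 44.7 and 46.1 for replicates 2 and 3. Leaving it out raised the calls to 5319 risen and 5326 fallen genes of 14916 tested, kept 8140 of the 8204 calls in the same direction and turned 0. Of 43 tested lists camera called 19. With an estimated correlation 4 of these were also called, mitosis and DREAM and E2F targets (adjusted p = 0.00299 each), interferon response (0.0113) and ribosome biogenesis (0.0397). Other splits of the same 6 libraries gave up to 25 lists, but they mix both groups on each side and so keep part of the change. Adjusted over the list alone, the counts of risen and fallen genes were 3 and 35 for ribosome biogenesis, 4 and 30 for the spliceosome, 21 and 2 for lysosomes, 20 and 3 for immediate early genes, and 19 and 4 for p53 targets. They were 12 and 8 for ATF4 targets, 3 and 8 for heat shock, and 6 and 7 for MAPK output. Mitochondrial lists had 4 and 3 for complex I, 3 and 1 for complexes II to V, 3 and 0 for mtDNA-encoded proteins, and 15 and 18 for the mitochondrial ribosome. Further counts were 0 and 1 for cytosolic ribosomal proteins, 1 and 1 for snoRNA hosts and 1 and 3 for T and NK cell markers. For every other list apart from MYC targets and monocyte genes, given above, the counts equalled those over all genes. Median, mean and camera direction differed in sign for the mitochondrial ribosome, NF-kB, MAPK and snoRNA host lists, which were not called.

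**Figure D2:**
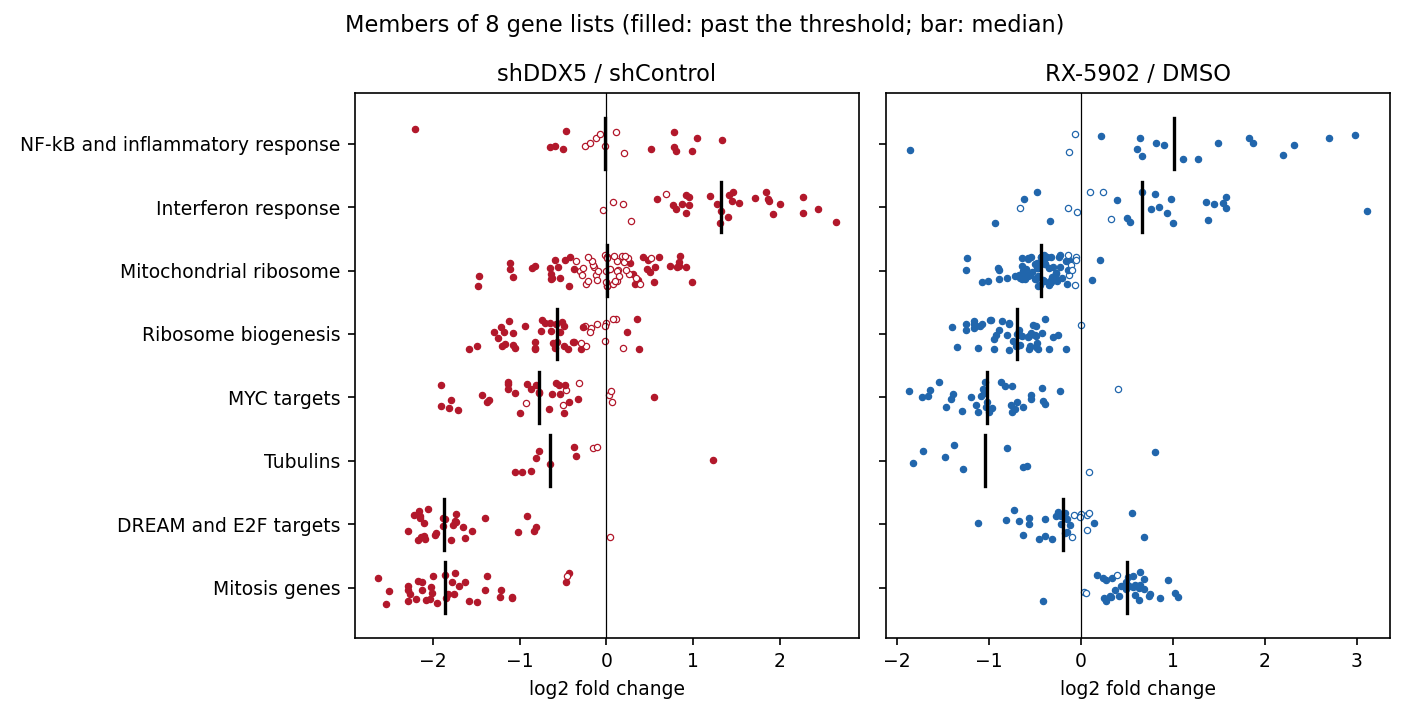
Log2 fold changes of the members of 8 gene lists in the knockdown and the drug experiment, filled where edgeR called the gene. The bars mark the medians.

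After 6 hours of RX-5902, MYC RNA was 4.06-fold lower than with DMSO (log2 -2.02, SE 0.04, 3 libraries per group, edgeR adjusted p = 8.73e-28), at 616 ± 27.7 CPM with DMSO and 152 ± 6.39 CPM with the compound. Targets of MYC, ribosome assembly and mitochondrial protein synthesis fell with it, while NF-kB targets rose. DDX5 did not fall. It stood at 854, 868 and 863 CPM with DMSO and at 1108, 1067 and 1023 CPM with RX-5902, a rise of 0.31 (SE 0.04, edgeR adjusted p = 1.47e-08). Against a fold of 1.2 this rise was not called (edgeR adjusted p = 0.104). In total edgeR called 8943 of 13941 genes (64.1%), 4492 risen and 4451 fallen, and 720 rose and 497 fell by at least 2-fold.

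Among protein-coding genes with a mean of at least 5 CPM and no overlap between groups, CREB5, a transcription factor that binds cAMP response elements (chr7:28299321-28825894), had the largest rise, at 33.8-fold (log2 5.08, SE 0.14), from 0.621 to 21.2 CPM. DUSP8, a phosphatase of stress kinases, rose 29.9-fold, LZTS3, a scaffold protein, 12.6-fold, the transcription factor JUN 10.0-fold, the chemokine CXCL10 8.65-fold and the protein kinase A inhibitor PKIB 7.34-fold. HPDL, an enzyme of coenzyme Q synthesis in mitochondria (chr1:45326895-45328710), had the largest fall under the same limits, at 5.99-fold lower (log2 -2.58, SE 0.11). The uracil glycosylase UNG was 5.18-fold lower, the growth factor BMP8B 4.8-fold, the mitochondrial phospholipase PLD6 4.73-fold, the actin-binding protein NEXN 4.54-fold and the clock repressor NR1D1 4.29-fold. NR1D1 shares 473 bases with THRA, BMP8B 80 bases with PPIE, and PLD6 overlaps MPRIP, so their levels carry some doubt.

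Of 35 MYC targets 34 fell and 0 rose with RX-5902 (median -1.02, camera adjusted p = 8.83e-44), among them ODC1 (-1.54) and SRM (-1.66) of polyamine synthesis and the nucleolar factor NOP16 (-1.87). Ribosome biogenesis genes fell in 48 of 49 cases and rose in 0 (median -0.69, camera adjusted p = 6.01e-32), such as WDR3 (-1.40), NOL6 (-1.34) and NAT10 (-1.09). In the DEAD-box list 25 of 34 fell and 5 rose (median -0.36, camera adjusted p = 2.51e-05, and adjusted p = 0.0530 with an estimated correlation), with DDX31 at -1.12 and DDX21 at -0.71. Spliceosome and SR protein genes had 27 of 45 fallen and 7 risen (median -0.16, camera adjusted p = 0.00658, and adjusted p = 0.0668 with an estimated correlation), including SRSF7 (-0.75) and SRSF1 (-0.57), and R-loop and decay factors 16 of 26 fallen and 3 risen (median -0.20, camera adjusted p = 0.00523, and adjusted p = 0.0668 with an estimated correlation), including EXOSC5 (-1.23). Hosts of snoRNAs had 11 of 16 fallen and 1 risen (median -0.63, camera adjusted p = 1.64e-05, and adjusted p = 0.0637 with an estimated correlation), for example SNHG15 (-1.42) and SNHG12 (-1.25). Cytosolic ribosomal protein genes had 11 risen and 7 fallen of 74 (camera adjusted p = 0.990).

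Nuclear genes for mitochondria fell broadly at 6 hours. Of 75 mitochondrial ribosome genes 66 fell and 2 rose (median -0.43, camera adjusted p = 6.03e-11), among them MRPL24 (-1.24) and MRPS25 (-1.07). Biogenesis genes fell in 24 of 28 and rose in 1 (median -0.61, camera adjusted p = 2.25e-13), including the mtDNA helicase TWNK (-1.36), the import channel TOMM40 (-1.09) and the coactivator PPRC1 (-1.05). In complex I 28 of 37 fell and 1 rose (median -0.28, camera adjusted p = 0.00523, and adjusted p = 0.184 with an estimated correlation), with NDUFAB1 at -0.70 and NDUFA8 at -0.54. For complexes II to V it was 35 of 40 and 0 (median -0.27, camera adjusted p = 5.98e-05, and adjusted p = 0.0637 with an estimated correlation), with the ATP synthase gene ATP5MC1 at -0.94 and cytochrome c CYCS at -0.61. TCA cycle genes fell in 16 of 20 and rose in 0 (median -0.25, camera adjusted p = 0.00149, and adjusted p = 0.0637 with an estimated correlation), such as IDH3A (-1.02). The 13 mtDNA-encoded genes had 12 fallen and 0 risen (median -0.24, camera adjusted p = 0.0833, 0.00456 without RX-5902 replicate 3, and 0.0444 with the replicate number as a block), with MT-CO1 at -0.26. Mitochondrial dynamics genes had 6 risen and 5 fallen of 19 (camera adjusted p = 0.0672, and 0.0374 without RX-5902 replicate 3), where the mitophagy receptor OPTN rose by 1.37 and MIEF1 fell by 0.85. MRPS25 shares 7157 bases with NR2C2.

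Heat shock genes and genes of the unfolded protein response also fell with RX-5902. Glycolytic genes had 13 of 20 fallen and 3 risen (median -0.31, camera adjusted p = 0.00139, and adjusted p = 0.206 with an estimated correlation), including hexokinase HK2 (-1.36) and LDHA (-0.89). Heat shock genes fell in 14 of 15 and rose in 1 (median -0.67, camera adjusted p = 2.36e-11), such as FKBP4 (-0.92) and HSPA8 (-0.75), and genes of the unfolded protein response fell in 18 of 20 and rose in 0 (median -0.42, camera adjusted p = 2.03e-10), such as XBP1 (-1.29) and HSPA5 (-0.94). ATF4 targets had 19 of 28 fallen and 4 risen (median -0.37, camera adjusted p = 4.69e-06, and adjusted p = 0.0637 with an estimated correlation), with the amino acid transporter SLC7A5 at -1.60, PSAT1 at -1.44 and the phosphatase regulator PPP1R15A at 1.47. Proteasome genes fell in 26 of 31 and rose in 0 (median -0.26, camera adjusted p = 0.000689, and adjusted p = 0.0755 with an estimated correlation), with PSMD7 at -0.46. Cholesterol synthesis had 13 of 20 fallen and 4 risen (median -0.22, camera adjusted p = 0.0466, and adjusted p = 0.175 with an estimated correlation), where DHCR7 fell by 0.96. The camera adjusted p of this list was 0.0509 and 0.0537 without DMSO replicate 1 and RX-5902 replicate 1. It was 0.0668 with library totals and 0.124 with the stricter filter. Fatty acid synthesis (3 rose and 6 fell of 10, FASN at -0.72), fatty acid oxidation (2 and 6 of 15, CPT1A at -0.62), NRF2 targets (8 and 7 of 19, ferritin FTH1 at 1.43) and hypoxia targets (4 and 5 of 12, BNIP3L at 0.83) had camera adjusted p values of 0.106, 0.485, 0.778 and 0.892.

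NF-kB and inflammatory genes rose in 15 of 18 cases and fell in 1 with RX-5902 (median 1.01, camera adjusted p = 1.99e-12), among them NFKB2 (2.21) and TNFAIP2 (1.88), while TNF fell by 1.85. Interferon genes had 17 of 27 risen and 4 fallen, 17 and 5 when adjusted over the list alone (median 0.66, camera adjusted p = 0.00322, and adjusted p = 0.0903 with an estimated correlation), with the RNA sensor IFIH1 at 1.39. Immediate early genes had 18 of 28 risen and 5 fallen (median 0.54, camera adjusted p = 0.00721, and adjusted p = 0.207 with an estimated correlation), led by JUN (3.32, SE 0.11). Targets of p53 rose in 16 of 28 and fell in 4 (median 0.25, camera adjusted p = 0.000522, and adjusted p = 0.0579 with an estimated correlation), with BTG2 at 2.64 and PHLDA3 at 1.08, and CDKN1A rose 2.25-fold (log2 1.17, SE 0.04), from 195 ± 7.40 to 439 ± 20.8 CPM. Lysosome and autophagy genes rose in 19 of 24 and fell in 2 (median 0.28, camera adjusted p = 1.31e-06, and adjusted p = 0.0755 with an estimated correlation), such as SQSTM1 (1.67), GABARAPL1 (1.58) and the regulator TFEB (1.30). MAPK output genes had 8 risen and 6 fallen of 16, with SPRY4 at -1.26, and STAT5 targets 5 and 4 of 11, with PIM1 at 0.66 (camera adjusted p = 0.990 each). Wnt targets had 3 and 3 of 9 (camera adjusted p = 0.2), with ZNRF3 at -1.60 and CTNNB1 at 0.22 (SE 0.04, not called against a fold of 1.2), and CCND1 was at 0.05 (edgeR adjusted p = 0.533).

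Cell division genes took an unusual form in RX-5902 cells. Mitosis genes rose in 32 of 36 and fell in 1 (median 0.51, camera adjusted p = 5.55e-12, and adjusted p = 0.0668 with an estimated correlation), such as the spindle gene ASPM (0.95) and the kinesins CENPE (1.02) and KIF4A (0.74). DREAM and E2F targets fell in 20 of 30 and rose in 3 (median -0.19, camera adjusted p = 0.00405, and adjusted p = 0.0668 with an estimated correlation), such as GINS2 (-1.12) and MCM2 (-0.81). Tubulin genes fell in 8 of 10 and rose in 1 (median -1.04, camera adjusted p = 2.25e-13, and adjusted p = 0.0560 with an estimated correlation), with TUBA1B at -1.82, TUBB4B at -1.71 and TUBB at -1.47. Replication-dependent histones rose in 6 of 7 and fell in 0 (median 1.49, camera adjusted p = 0.0384, and adjusted p = 0.141 with an estimated correlation), with H2AC6 at 2.10 and H2BC21 at 1.81. Only these 7 of 31 listed histones passed the expression filter, and they summed to just 5.29 CPM with DMSO and 16.1 CPM with RX-5902. Tubulin and histone genes have near-identical copies, which makes single values uncertain.

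BCL2 was 1.95-fold lower with RX-5902 (log2 -0.96, SE 0.04, edgeR adjusted p = 4.22e-19), at 138 ± 2.58 CPM with DMSO and 70.8 ± 3.86 CPM with the compound. MCL1 rose by 0.20 (SE 0.04), BCL2A1 by 0.74 (SE 0.12), and BBC3 rose 2.01-fold (log2 1.01, SE 0.09). BCL2L1 rose by 0.25 (SE 0.09, edgeR adjusted p = 0.0121), with adjusted p values of 0.0995 and 0.0844 without DMSO replicates 2 and 3 and of 0.0623 and 0.0537 without RX-5902 replicates 1 and 3. DESeq2 did not call it (0.23, adjusted p = 0.100), and against a fold of 1.2 neither it (0.546) nor the rise of MCL1 was called. BMF, a BH3-only sensor of stress, rose by 2.83, and the BH3-only genes BCL2L11 and BID fell by 0.79 and 0.61. BAX was at 0.09 (edgeR adjusted p = 0.0809, but 0.00514 to 0.0251 in 5 alternatives, such as 0.00982 without RX-5902 replicate 1), and PMAIP1 at -0.12 (0.0963 with edgeR). As lists, 4 of 5 anti-apoptotic genes rose and 1 fell (camera adjusted p = 0.990), and 3 of 10 pro-apoptotic genes rose and 3 fell (0.294).

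Granule genes of myeloid cells fell with RX-5902. Granulocyte genes fell in 13 of 13 cases (median -0.62, camera adjusted p = 2.33e-07, and adjusted p = 0.0707 with an estimated correlation), with PRTN3 at -1.45, ELANE at -0.93 and CTSG at -0.79. KMT2A-fusion and stemness genes rose in 15 of 21 and fell in 3 (median 0.28, camera adjusted p = 0.0414, and adjusted p = 0.133 with an estimated correlation), with JMJD1C at 0.78, ZNF521 at 0.48 and MYB at -0.77. The camera adjusted p of this list was 0.0545 without DMSO replicate 2, 0.0575 with the stricter filter and 0.0515 after the length correction. Monocyte genes had 13 risen and 6 fallen of 22 (camera adjusted p = 0.178), with ITGAX at 1.82 and the transcription factor IRF8 at -1.31, and HLA class I genes 8 and 3 of 11 (0.164), with HLA-B at 0.43 and TAP2 at -0.69. Of the lists too small to test, T and NK cell markers summed to 36.7 ± 1.09 CPM with DMSO and 78.7 ± 2.48 CPM with RX-5902 (n = 3; TRAC rose by 1.29), packaging and epithelial markers to 4.77 ± 0.453 and 20.4 ± 1.36 CPM (L1CAM rose by 2.27), and erythroid markers to 15.8 ± 1.18 and 25.6 ± 0.546 CPM (EPOR rose by 0.63). Mast cell and eosinophil markers summed to 14.1 and 10.9 CPM, fibroblast markers to 4.90 and 5.74 CPM, B cell markers to 2.79 and 3.46 CPM, and megakaryocyte markers to 3.60 and 3.36 CPM, and of 3 HLA class II genes none was called by edgeR. TRAC, L1CAM and EPOR were chosen as examples after their values were seen. Camera called 28 of 42 lists, and 7 of them held with an estimated correlation: MYC targets, ribosome biogenesis, mitochondrial biogenesis and mitochondrial ribosome (0.0104 each), and heat shock, unfolded protein response and NF-kB (0.0119 each). Adjusted over the list alone, the counts of risen and fallen genes were 1 and 29 for complex I, 0 and 36 for complexes II to V, 2 and 67 for the mitochondrial ribosome, and 0 and 17 for the TCA cycle. They were 5 and 26 for DEAD-box helicases, 16 and 3 for stemness genes, 8 and 5 for cytosolic ribosomal proteins, 4 and 6 for fatty acid synthesis and 5 and 5 for hypoxia targets. Apart from interferon genes, given above, the other lists had the same counts as over all genes. Median, mean and camera direction differed in sign for the BCL2 family, Wnt, MAPK, STAT5, hypoxia and cytosolic ribosomal protein lists, which were not called.

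**Figure D3:**
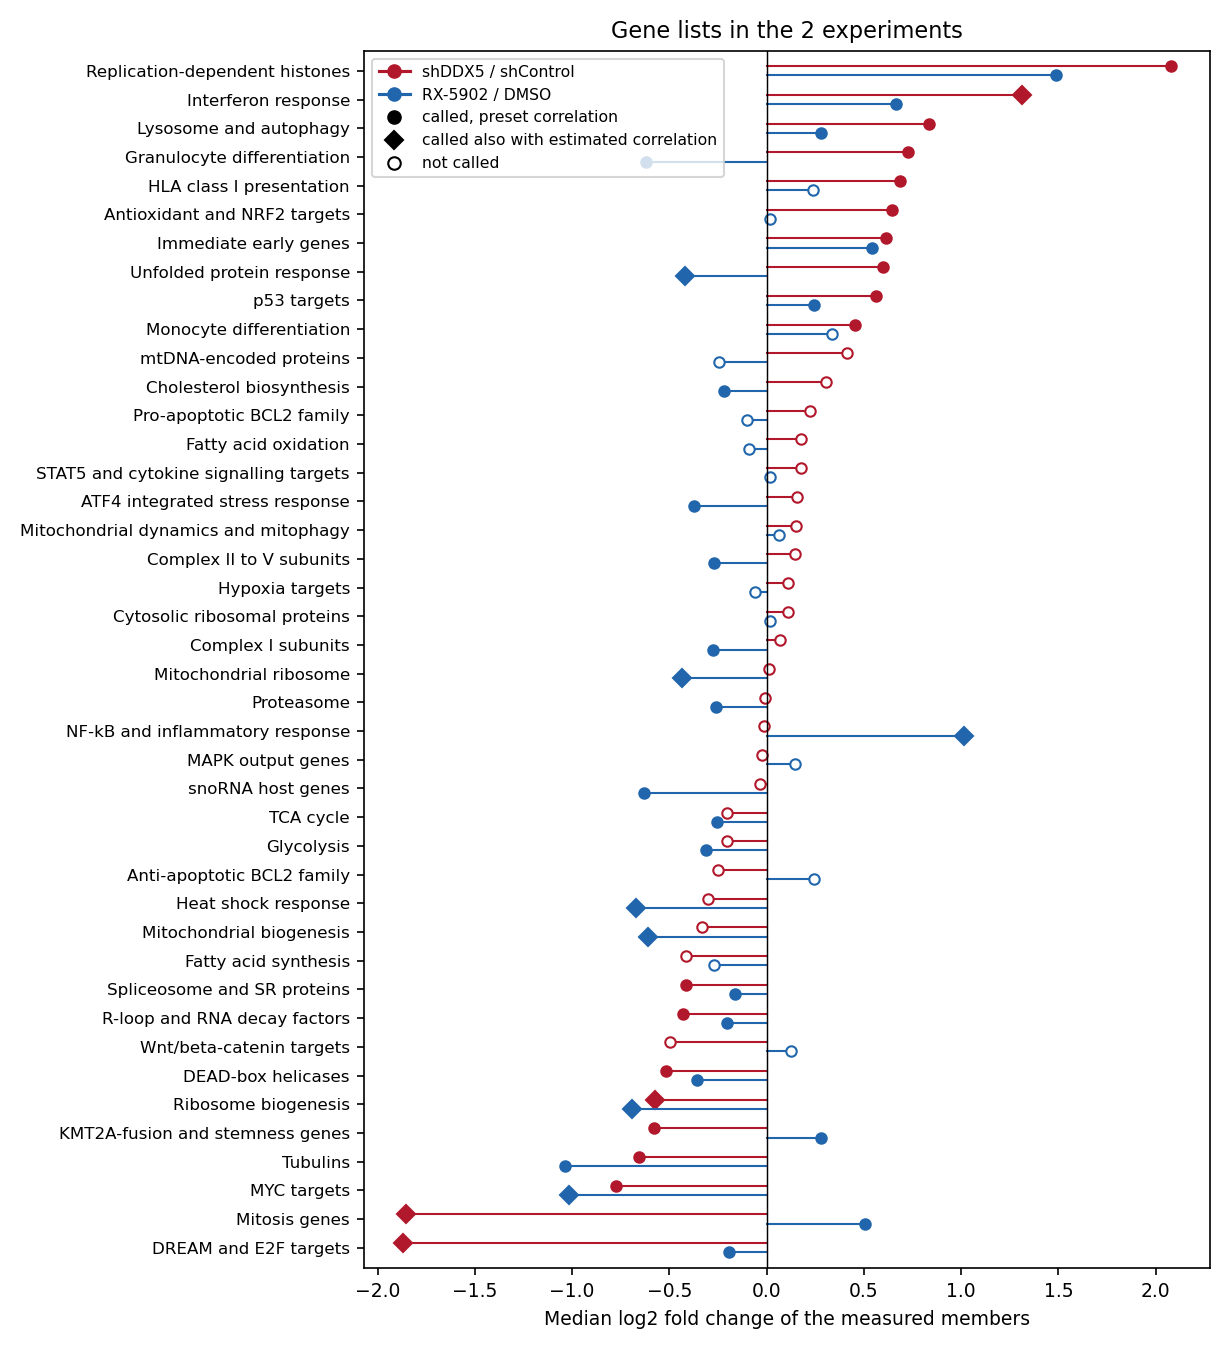
Median log2 fold change of each gene list in the knockdown and the drug experiment. Filled points were called by camera, diamonds also with an estimated correlation.

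BCL2 fell and CDKN1A rose both after the knockdown and after the compound, and MYC fell in both. For BCL2 the change in shDDX5 minus that in RX-5902 was 0.07 on the log2 scale (edgeR adjusted p = 0.636), for CDKN1A 0.23 (0.153) and for BCL2L1 0.30 (0.0870). Equality of the changes was not tested, and the standard errors of these 3 differences were 0.115, 0.131 and 0.140. Of 13233 genes tested in both experiments, 3068 were called in the same direction, against 2474 expected of independent lists, and 2112 in opposite directions. The 1370 genes that rose in both compare with 1152 expected (odds ratio 1.45), and the 1698 that fell in both with 1322 (odds ratio 1.81). Across all these genes the fold changes had a Pearson correlation of 0.125 and a Spearman correlation of 0.132. Genes are not independent of each other, and a Pearson correlation at least as large in absolute value was reached in 33 of 100 pairs of splits of the libraries. These splits still held part of the real changes, so they cannot decide on chance, which is not excluded.

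JUN rose by 2.68 and 3.32 in shDDX5 and RX-5902, the filamin-interacting FILIP1L by 2.87 and 2.51, the prostaglandin receptor PTGER4 by 2.05 and 2.46, the noncoding FMNL1-DT by 2.13 and 1.76 and the glucocorticoid-induced TSC22D3 by 1.75 and 1.75. SLC29A1, a nucleoside transporter that carries cytarabine into cells, fell by 1.92 and 2.01, TNF by 2.20 and 1.85, the adhesion gene FERMT1 by 1.57 and 1.64, NEXN by 1.56 and 2.18 and the transcription factor BATF3 by 1.43 and 1.59. Mitosis genes, granulocyte genes, the unfolded protein response and the stemness list were called by camera in opposite directions at the preset correlation. With an estimated correlation none of them was called in both experiments, at adjusted p values in shDDX5 and RX-5902 of 0.00299 and 0.0668, 0.230 and 0.0707, 0.126 and 0.0119, and 0.126 and 0.133. FMNL1-DT shares sequence with FMNL1 on the other strand.

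The change differed between the experiments for 8108 of 15386 genes (edgeR, difference test), 3710 higher and 4398 lower in the knockdown, and the 2112 genes with opposite calls were all among them. SLPI was at 4.26 in shDDX5 and -1.18 in RX-5902, CREB5 at -1.77 and 5.08, the microtubule gene MAP1A at -2.50 and 2.75, and the secreted ANGPTL2 at -3.83 and 1.16. The antisense gene ENSG00000259094 and the actin-binding LSP1 rose by 4.67 and 2.22 in the knockdown and were too low for a test with RX-5902, so no size is given for their difference here. Time of exposure (96 and 6 hours) and the delivery by virus differ along with the agent, so the cause of a difference cannot be told from these data.

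**Figure D4:**
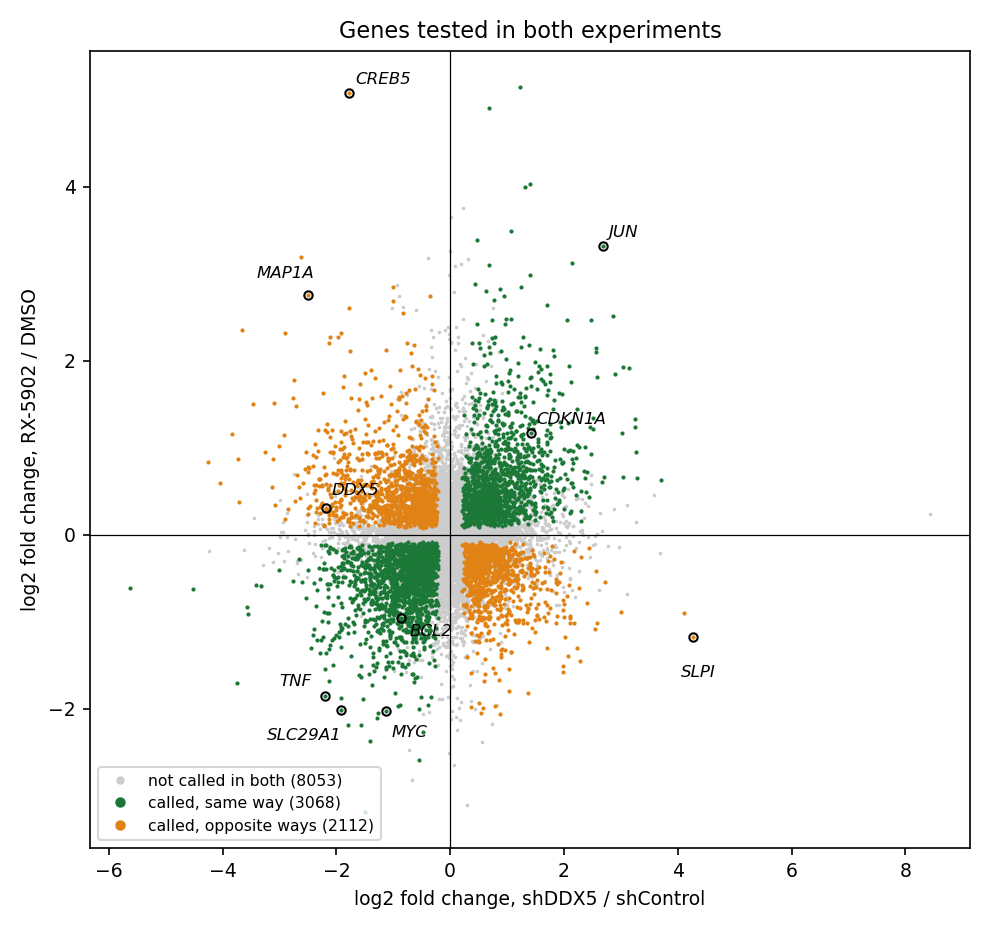
Log2 fold change of each gene in the knockdown against that in the drug experiment, with 3068 genes called in the same direction and 2112 in opposite directions. The other 8053 genes were not called in both.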

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

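For the tubulins the test of dividing cells, for the histones those of RNAs without poly(A) tails and of S phase, and for shDDX5 replicate 1 those of the degree of knockdown and of length as the whole cause were chosen only after the results were seen.

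Tubulin genes fell at 6 hours of RX-5902, and autoregulation of tubulin RNA by free tubulin might explain it, as when microtubules come apart. The alpha and beta tubulins had a median log2 fold change of -1.38, which is -0.79 relative to TUBG1, TUBD1 and TUBE1 (median -0.59), with 6 of 7 fallen, yet TUBG1 and TUBE1 also fell and TUBA1A rose by 0.80. In shDDX5 cells the order was the other way, at -0.36 and -0.81. Fewer cells with mitosis transcripts would not give it, since the mitosis list had a median of 0.51 (lower quartile 0.33). DREAM and E2F targets fell, however (median -0.19), so the mitosis list cannot tell whether fewer cells completed division. Reads shared only among the neighbouring alpha-tubulin copies would not give it either, since 3 beta-tubulin genes at other loci fell. Sharing among near-identical copies at other loci is not excluded, since the handling of multi-mapping reads is not known. After a correction for exon length 100% of the fallen alpha and beta genes were still called (median -1.37).

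Most of the few histone genes measured rose in both experiments, and a larger recovery of RNAs without poly(A) tails could raise them without a change in the cells. Other nuclear RNAs without tails had a median log2 fold change of -0.0058 in shDDX5 (39 measured, 6 rose and 4 fell, quartiles -0.62 and 0.38). In RX-5902 the median was -0.69 (29 measured, 1 rose and 14 fell). Most of these RNAs lie near the detection limit (control median of 0.873 CPM in each experiment). The most abundant of them in the knockdown experiment, RN7SL1, chosen after its value was seen, rose there from 8.11 to 51.4 CPM (log2 2.66, edgeR adjusted p = 0.0118). With RX-5902 it was at 0.04 and not called. Recovery therefore stays open in both experiments, a stricter reading for RX-5902 that was adopted after the value was seen. More cells in S phase would raise the replication list, whose median was -1.87 in shDDX5 (upper quartile -1.64) and -0.19 in RX-5902 (upper quartile -0.02). The risen histones were still called after a length correction in 100% of cases in both experiments (medians 1.81 and 1.55).

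Replicate 1 of shDDX5 may have had RNA or a library of other quality, as its deviation from replicates 2 and 3 followed exon length (r = -0.53, median 0.47 in the 10% shortest genes, up to 2152 bases, and -0.37 in the 10% longest, from 12155 bases). Length was not the whole of it, since the spread of the deviation over that expected from replicates 2 and 3 was 4.00 for 9981 genes and 3.38 after the length trend was taken off. Its DDX5 level was close to theirs (ratio 0.980), and without 181 mitochondrial and ribosomal protein genes the spread ratio was 3.97. Its deviation followed the change in replicates 2 and 3 only weakly (r = 0.156 over 6141 genes). As replicate 1 lay further out on the first principal component (63.1 against 44.7 and 46.1), a position further along the same change is not excluded for it. Between it and the others 11 genes were at least 2-fold higher and 222 lower, against 0 between replicates 2 and 3. GC content did not track the deviation (r = 0.081 over 9957 genes with a transcript sequence), and with length and GC trends both taken off the spread ratio was 3.32.

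The libraries were regrouped to set the counts of genes and lists beside those of other splits. With 6 libraries there are only 10 splits, too few for a share under 0.05. In every other split both sides mixed treated and control libraries in unequal numbers. Part of the real change therefore stayed in the comparison and part in the spread, so these splits are not a reference free of the treatment. The real split was the 1 of 10 with at least 8204 genes in the knockdown and the 1 of 10 with at least 8943 in the drug experiment, with 0 genes in any other split by edgeR, where unadjusted p values under 0.05 numbered 14 to 225 and 50 to 110. For lists called by camera, 7 of 10 splits reached the real 19 in the knockdown (highest other 25), and 1 of 10 reached the 28 of the drug experiment (highest other 25). Lists moved by the treatment can be called in those splits as well, so these counts do not tell whether the real calls go beyond chance. The correlation of 0.125 between experiments was reached in absolute value in 33 of 100 pairs of splits (highest other 0.176). Since those splits carry part of the real changes, this share cannot decide on chance, which is not excluded. For genes called in the same direction the count was 1 of 100 (3068, highest other 2112), drawn after a first run over 200 signed pairs. Since edgeR called no gene in the other splits of either experiment, that count could hardly have come out otherwise and says nothing on whether the shared direction goes beyond chance. For the difference it was 2 of 100 (8108), the other being the real grouping with the labels of 1 experiment exchanged, with 8891 genes. In the 82 drawn splits that kept the real grouping of neither experiment the highest count was 0. The share for the difference therefore does not decide on chance either.

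The named genes whose change differed between the experiments are given as the log2 fold change in shDDX5 minus that in RX-5902, with the edgeR adjusted p. DDX5 was at -2.51 (1.55e-10), DDX17 at -0.60 (4.03e-05), the survival gene MCL1 at -0.62 (6.90e-05), and the BH3-only genes BBC3 at -0.66 (0.0217) and PMAIP1 at 0.44 (0.00304). MYC was at 0.88 (4.41e-06), CCND1 at -2.46 (6.75e-09) and CTNNB1 at 0.39 (0.00167). Among genes called in the same direction in both, JUN was at -0.66 (0.00857), PTGER4 at -0.43 (0.0289), TNF at -0.37 (0.0271) and NEXN at 0.60 (0.0427). SLPI was at 5.42 (4.96e-09), CREB5 at -6.87 (6.85e-10), MAP1A at -5.27 (7.17e-10) and ANGPTL2 at -5.01 (3.52e-10). ENSG00000259094 at 6.00 (SE 1.54, 0.00459) and LSP1 at 5.36 (SE 1.74, 0.0209) had almost no counts in the drug experiment, so these fitted values are not sizes of a difference.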

How the results depend on the processing

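All settings below were planned before the data were examined, and none was added after the results were seen. DDX5 stayed between -2.27 and -2.02 on the log2 scale in every setting, and between -2.21 and -2.18 when any 1 library was left out. In these settings no call of a named gene or list turned its direction. Over 157 named genes the edgeR call was the same in 2623 comparisons in the knockdown, weaker in 32 (8 genes) and stronger in 2 (1 gene), and for RX-5902 the same in 2631, weaker in 21 (9 genes) and stronger in 5 (1 gene). For lists the counts were 442, 17 (15 lists) and 13 (5 lists) in the knockdown, and 429, 29 (21 lists) and 3 (2 lists) for RX-5902.

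The lists changed most when the correlation between genes was estimated from the data. Camera then called 4 lists in the knockdown in place of 19, and 7 with RX-5902 in place of 28. Correlated genes alone do not account for this, since some lists lost their call at estimated correlations below the preset 0.01. Examples in the knockdown were the unfolded protein response (-0.041) and R-loop and decay factors (-0.014). The mitosis list there had an estimated correlation of -0.0040, yet its camera adjusted p went from 3.78e-36 to 0.00299. The adjusted p values with an estimated correlation are therefore stricter for reasons other than gene correlation, and are not a measure of it alone. A test against a fold of 1.2 left 6378 genes in the knockdown and 5190 with RX-5902, where the rise of DDX5 was no longer called (adjusted p = 0.104, the highest of 17 alternatives, the lowest being 1.74e-15), nor was the fall of MCL1 in the knockdown (0.0648, the lowest being 1.80e-07). DESeq2 called 7808 and 7578 genes, DESeq2 size factors 8198 and 8940, library totals 8102 and 9072, no filter 8110 and 9074, the stricter filter 6344 and 7370, protein-coding genes alone 6968 and 7882, the length correction 8651 and 8983, and 1 fit of all 12 libraries 9672 and 6816. In that joint fit MT-CO1 was not called with RX-5902 (0.157, with a range over alternatives of 3.97e-12 to 0.493). With library totals the median log2 fold change moved to -0.09 in the knockdown and 0.07 with RX-5902, and the risen share of called genes to 43.9% and 57.6%. The histone list with RX-5902 was then not called (0.0564, range 0.0229 to 0.141), nor the monocyte list in the knockdown (0.0504, range 0.00723 to 0.247). BCL2A1 in the knockdown was not called after the length correction (0.340).

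Replicate numbers did not pair the libraries, with correlations of -0.09, -0.19 and 0.07 in the knockdown and -0.19, 0.06 and -0.25 with RX-5902. As a block they gave 7592 and 8696 genes, 21 and 29 lists, 2813 genes in the same direction and 7626 that differed, and with the length correction 8216 and 8727 genes. Leaving out 1 library gave 6676 to 10645 genes and 19 to 22 lists in the knockdown, 8413 to 8691 genes and 27 to 30 lists with RX-5902, 2514 to 4081 genes in the same direction, correlations of 0.102 to 0.141 and 7461 to 9537 genes that differed. Genes in the same direction numbered 2572 with DESeq2, 3018 with library totals, 2582 with the stricter filter, 3333 with the length correction and 2248 at a mean of at least 10 CPM.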

Other observations

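Lists in this part were written, and their tests and the genes named from them chosen, only after the gene results had been seen, and all but the nucleotide synthesis list were tested without the genes that prompted them. For nucleotide synthesis no gene was left out, so its test is not independent of the results that prompted it. The other lists were also written with the results in view, and all but the clock list share genes with the fixed lists. Their tests are therefore not independent evidence either. Nucleotide synthesis genes fell in 22 of 24 cases and rose in 0 after 6 hours of RX-5902 (median log2 fold change -0.71, camera adjusted p = 1.35e-15, and adjusted p = 0.00483 with an estimated correlation). The pyrimidine enzyme DHODH, which sits in the inner mitochondrial membrane, fell by 1.39 and the purine enzyme PFAS by 1.22. Of the 24 genes 6 are also in the fixed lists, and 18 of the other 18 fell. Subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, and initiation factors of polymerase I together fell in 17 of 23 cases and rose in 2 (median -0.61, camera adjusted p = 6.44e-09, and adjusted p = 0.0120 with an estimated correlation), with POLR1A at -1.08, POLR1B at -1.19 and POLR3G at -1.42, and 3 of the 23 are in fixed lists. These were prompted by POLR1G at -2.05.

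FOXO target genes rose in 15 of 20 cases and fell in 3 with RX-5902 (median 0.59, camera adjusted p = 1.80e-06, and adjusted p = 0.0130 with an estimated correlation). The thioredoxin inhibitor TXNIP rose by 1.53, the ubiquitin ligase adaptor KLHL24 by 1.45 and the transcription factor KLF6 by 1.47, and the list was prompted by BCL6 (2.74), CCNG2 (2.27) and BMF (2.83). Of its 20 genes 6 are in the fixed lists, and 11 of the other 14 rose. Clock output genes had 6 of 8 fallen and 2 risen and were not called (camera adjusted p = 0.0969), with NR1D2 at -1.08, PER2 at -0.77 and CIART at 1.86, prompted by NR1D1 and TEF (-1.98).

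In a list of eosinophil genes 4 of 5 rose and 0 fell in shDDX5 cells (median 1.76, camera adjusted p = 0.00313, and adjusted p = 0.122 with an estimated correlation). The list holds regulators such as GATA2 (-0.17, not called) as well as granule proteins. The risen HDC lay near the detection limit, at 0.0329 CPM in shControl and 0.703 CPM in shDDX5. The granule ribonuclease RNASE2 rose by 1.76, the peroxidase EPX by 3.10 and the maturation factor CEBPE by 1.52, prompted by RNASE3 at 2.56, and 4 of the 5 are in fixed lists. Secreted granule ribonucleases and proteases rose in 6 of 10 and fell in 0 (median 0.60, camera adjusted p = 0.00313, and adjusted p = 0.411 with an estimated correlation), with ELANE at 2.11, PRTN3 at 2.28 and CST3 at 1.83, and 4 of the 10 are in fixed lists.

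A hypothesis for RX-5902 is that the fall of alpha and beta tubulins relative to the other tubulins (-0.79) could come from free tubulin, which a measure of tubulin polymer in treated cells would test. RNA levels alone do not settle it, and they say nothing of the phosphorylated form of DDX5.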
